A study of Mus musculus with 9 samples.

How the data were processed

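Brain RNA of 9 mouse samples was analysed, 3 each from untreated brain and from brain after photodynamic therapy with 5-ALA at 10 and at 20 J/cm2. Groups were taken from the sample labels, and all 9 libraries were used. The deposited table gives 54153 genes with Ensembl mouse gene identifiers, symbols (352 have none), coordinates, lengths and FPKM values, computed by the authors on Illumina reads of total RNA. Per the submitters' processing notes Bowtie 0.12.2 and the mm8 genome were used, without saying at which step. The program that made the FPKM values is not named in the sources used. Coordinates were compared with a GENCODE reference on GRCm38: 53620 identifiers (99%) were found there, 97.1% of them with identical coordinates, so coordinates are given on GRCm38.

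FPKM times gene length came to whole reads for 100% of values (tolerance 0.02 reads). This gave 15.05 to 17.51 M reads per library, and the authors' per-million totals were 0.983 to 1.021 times those sums. At this depth, counting noise matters mainly for genes with few reads, such as short RNAs, for which reads per library are given. Within groups, pairs of libraries had a chi-square of 2.98 to 9.71 per gene, so none was a copy of another. The pairs lay at 2.98 to 3.86 in untreated, 3.45 to 3.81 at 10 J/cm2 and 7.02 to 9.71 at 20 J/cm2, where libraries differed most. Libraries correlated at r = 0.970 or more in all pairs.

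The plan written before the data were examined assumed a table of counts and named a fallback for normalized values. Since the deposited values are FPKM, the fallback was used. Fixed at that point were the test, the filter, the threshold, the gene lists, the rule for named genes and the alternatives, except those stated here as added. FPKM values were transformed to log2(FPKM + 1), on which fold changes understate differences of genes at low levels. Genes at 1 FPKM or more in at least 3 libraries were kept, 14626 in all. Linear models with 1 mean per group over all 9 libraries were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (trend). P-values were adjusted over all tested genes by the Benjamini-Hochberg method, at a threshold of 0.05. Each dose was compared with untreated, and the doses with each other.

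Gene lists (44 lists with 734 genes, fixed before the data were examined) were tested with camera at a preset correlation of 0.01 where 3 or more members were measured, which left 39 lists. P-values were adjusted over the lists of a comparison. Since camera at a preset correlation is liberal for genes that are regulated together, each list was also tested with its correlation estimated from these libraries. Members were counted past the threshold over all genes and again adjusted over the list alone. Genes in the text were named by a fixed rule. Per comparison it took the 8 largest changes in each direction (5 for 20 against 10 J/cm2) among genes past the threshold, at 1 FPKM or more in the higher group and with no overlap between libraries of the groups, leaving out unnamed models and pseudogenes. It added up to 4 members with the smallest p of each described list, and Fos, Hmox1, Hspa1a, Alas1, Cldn5 and Gfap in all cases. Genes named outside the rule are stated as such.

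Alternatives fixed beforehand were quantile normalization, no filter, a filter of 5 FPKM, a pseudocount of 0.1, a fit of the 6 libraries compared, each library left out in turn, the replicate number as a block, a log2 fold change of at least 1, an estimated correlation and fry for lists. Added after the data were seen were limma-voom on the recovered reads, removal of each library's trend with GC content and length (GC content was known for 14372 genes, 98.3%), only genes of 300 bases or more, scaling to a median log2 ratio of 0, and leaving out the 2 libraries at 20 J/cm2 with the highest mitochondrial share. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

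The workflow was tested on simulated data with 200 changed genes. It called 152 genes, of which 4.6% were false, and found 61% of the 1.5-fold and 84% of the 2-fold changes. With a GC trend added to 1 group 320 genes were called and 51.6% were false, and after trend removal 158 were called and 10.1% were false. With limma-voom 74% were false under that trend. A comparison with no change gave 1 call. A simulated list at a fold change of 1.2 had a camera adjusted p of 4.54e-15, and 0 other lists were called. Simulated genes varied independently of each other and with the same dispersion in all groups. The simulation therefore cannot show how many false calls arise from genes that vary together or from a group with a wider spread.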

Results

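Photodynamic therapy with 5-aminolevulinic acid (5-ALA) supplies a heme precursor that cells turn into the photosensitizer protoporphyrin IX, which generates reactive oxygen species under red light. RNA from mouse brain tissue was sequenced in 3 groups of 3 libraries: untreated, light at 10 J/cm2 and light at 20 J/cm2. Per the labels, 5-ALA was given at 20 mg/kg, the 635 nm laser followed after 30 min, and brains were taken 90 min later after perfusion with saline. The same protocol text stands beside all 9 samples, so whether untreated mice received 5-ALA or sham handling is not stated. The labels name both BALB/c and C57BL/6 as the strain. Nothing says that the replicates came from separate animals, and p-values therefore measure only the spread between these samples, which may be technical.

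Sequencing depth on genes averaged 17.3 ± 0.248 M reads in untreated libraries, 16.03 ± 0.75 M at 10 J/cm2 and 15.6 ± 0.649 M at 20 J/cm2 (SD, n = 3). Genes at 1 FPKM or more numbered 14135 ± 23.4, 14122 ± 67.5 and 14072 ± 45.9 in the same order. Libraries of a group correlated across genes at r = 0.980 to 0.988, and each pair of a group differed by more than counting noise. Transcripts of the mitochondrial genome took 3.49 ± 0.11% of reads in untreated libraries, 3.49 ± 0.062% at 10 J/cm2 and 4.41 ± 0.466% at 20 J/cm2. The 20 J/cm2 libraries held 3.88%, 4.62% and 4.74%, all above the untreated ones (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Fold changes at 20 J/cm2 also followed the GC content of transcripts (Spearman rho = -0.515 across genes, which are not independent replicates), while at 10 J/cm2 rho was -0.131.

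**Figure D1:**
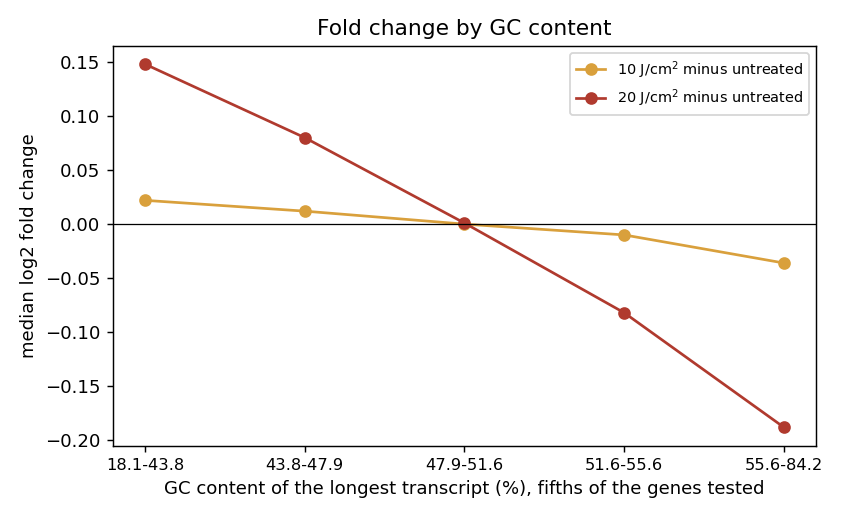
Median log2 fold change against untreated (vertical axis) of the genes tested, split into 5 equal groups by the GC content of the longest transcript in percent (horizontal axis); each point is the median of such a group and each line a light dose. At 20 J/cm2 the medians run from 0.15 in the group lowest in GC to -0.19 in the highest, and at 10 J/cm2 from 0.02 to -0.04.

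Comparing 10 J/cm2 with no treatment asks which brain transcripts differ after the lower light dose. Genes induced by glucocorticoid hormones rose together: of 13 measured list members, 9 rose, 0 fell and 4 did not pass the test. Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, GRCm38 chromosome 17 from 28399095 to 28517524), rose from 4.12 ± 0.252 to 16.5 ± 0.346 FPKM (SD, n = 3). Its log2 difference was 1.77 ± 0.06 (SE), with a limma adjusted p of 6.26e-06. Plin4, a lipid droplet coat protein (ENSMUSG00000002831, chromosome 17 from 56100591 to 56109803), rose from 0.677 ± 0.0656 to 5.45 ± 0.911 FPKM (log2 difference 1.93 ± 0.12, adjusted p = 0.000396). Cdkn1a, an inhibitor of cyclin-dependent kinases (ENSMUSG00000023067, chromosome 17 from 29090979 to 29100722), rose from 6.26 ± 1.53 to 25.4 ± 1.34 FPKM (1.88 ± 0.22, adjusted p = 0.00457). The transcription factors Zbtb16 (1.18, adjusted p = 0.00103) and Hif3a (1.03, adjusted p = 0.00244) and the kinase Map3k6 (1.38, adjusted p = 0.00244) also rose. The list had a median log2 difference of 0.67 and a camera adjusted p of 8.5e-17, and the call held with an estimated correlation (adjusted p = 0.0308). In the count adjusted over the list alone, 11 members rose and 0 fell. All 6 genes named from this list kept their call whichever library was left out.

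Immediate early genes, which cells transcribe within minutes of a stimulus, were lower as a list at 10 J/cm2: of 32 measured, 6 fell, 1 rose and 25 did not pass. The list's camera adjusted p was 0.00983, and adjusted p = 0.917 with an estimated correlation. Btg2, an antiproliferative protein (ENSMUSG00000020423, chromosome 1 from 134075170 to 134079120), fell from 17.0 ± 5.51 to 6.02 ± 0.335 FPKM (-1.31 ± 0.20, adjusted p = 0.0127). Dusp1, a phosphatase of MAP kinases, fell from 31.8 ± 4.81 to 15.2 ± 1.5 FPKM (-1.01 ± 0.15, adjusted p = 0.0127). The AP-1 subunit Junb (-1.06, adjusted p = 0.0168), Ier2 (-1.04, adjusted p = 0.0179), the matricellular protein gene Cyr61 (-1.02, adjusted p = 0.0334) and the orphan nuclear receptor Nr4a1 (-0.85, adjusted p = 0.0449) fell as well. The member that rose was Klf4 (0.53, adjusted p = 0.0387), named after its values were seen. Fos, the classic marker of neuronal activity, was at 32.9 ± 2.34 FPKM untreated and 15.7 ± 3.2 FPKM at 10 J/cm2 and did not pass (-1.04 ± 0.33, adjusted p = 0.163). The count adjusted over the list alone was 4 higher and 14 lower. With 1 library fewer the folds stayed about as large but calls were lost: Nr4a1 (-0.75 to -0.99) lost its call without any 1 of the 6 libraries (adjusted p 0.0503 to 0.153), Junb (-0.92 to -1.23) without any but 10 J/cm2 library 1 (up to 0.0769), and Cyr61 (-0.88 to -1.30) without any but untreated library 3 (up to 0.127). Klf4 (0.43 to 0.64) lost it without any but untreated library 3 (up to 0.129), Btg2 (-1.13 to -1.59) without untreated library 2 or 10 J/cm2 library 1 or 3 (up to 0.0559), Dusp1 (-0.90 to -1.10) without untreated library 1 or 10 J/cm2 library 2 or 3 (up to 0.057), and Ier2 (-0.86 to -1.16) without untreated library 1 or 2 (up to 0.0784).

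Genes of the blood-brain barrier moved in both directions at 10 J/cm2. Mfsd2a, the lipid transporter that restrains transcytosis in brain endothelium (ENSMUSG00000028655, chromosome 4 from 122946850 to 122961188), rose from 10.2 ± 0.528 to 17.5 ± 0.852 FPKM (0.72 ± 0.06, adjusted p = 0.00166). The glucose transporter gene Slc2a1 (0.69, adjusted p = 0.00219) and the efflux pump gene Abcc4 (0.51, adjusted p = 0.0111) rose, while the organic anion transporter gene Slco1a4 fell (-0.69, adjusted p = 0.00391). These were the 4 of 17 barrier transporters that passed over all genes. The same transporters adjusted over the list alone gave 3 higher and 3 lower, and the list as a whole was not called (camera adjusted p = 0.958). Of 19 basement membrane and matrix genes, 4 rose and 0 fell: the collagen IV genes Col4a1 (0.80, adjusted p = 0.00154) and Col4a2 (0.51, adjusted p = 0.0143), the laminin gene Lamc1 (0.44, adjusted p = 0.0101) and the protease inhibitor gene Timp3 (0.44, adjusted p = 0.0265). That list was not called (adjusted p = 0.711), and adjusted over the list alone 4 rose and 1 fell. Of 17 endothelial markers, Ly6c1 rose (0.46, adjusted p = 0.0146) and 4 fell: Slco1a4, the receptor genes Kdr (-0.61, adjusted p = 0.0116) and Eng (-0.37, adjusted p = 0.0198), and Tek (-0.40, adjusted p = 0.0199), the last named after its values were seen. Adjusted over the list alone 3 rose and 7 fell. The endothelial list was lower (median -0.09, camera adjusted p = 0.0157), and adjusted p = 0.333 with an estimated correlation. None of 17 junction genes passed over all genes or adjusted over the list alone, and Cldn5, the main claudin of brain endothelium (ENSMUSG00000041378, chromosome 16 from 18776847 to 18778260), was at 21.7 ± 2.44 FPKM untreated and 14.9 ± 2.11 FPKM at 10 J/cm2 (-0.51 ± 0.18, adjusted p = 0.212). Gkn3, a marker of arterial endothelium, fell (-1.13, adjusted p = 0.0259), with 66 to 91 reads per untreated library and 21 to 26 at 10 J/cm2. Calls lost without 1 library were Gkn3 and Tek (any of the 6; adjusted p up to 0.105 and 0.0932), Abcc4 (10 J/cm2 library 1, 0.0503), Lamc1 (untreated library 1, 0.0543), Col4a2 (any but 10 J/cm2 library 3, up to 0.0626) and Timp3 (any but 10 J/cm2 library 2, up to 0.103). The others were Kdr (untreated library 1 or 3 or 10 J/cm2 library 1, up to 0.0543), Ly6c1 (untreated library 1 or 2 or 10 J/cm2 library 1 or 2, up to 0.075), Eng (any but untreated library 2, up to 0.086) and the endothelial list (10 J/cm2 library 3, 0.056).

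Several other lists were called at 10 J/cm2 with few or no single genes past the threshold. Among 21 genes of the p53 response and apoptosis, 3 rose and 0 fell, namely Cdkn1a, the stress protein gene Trp53inp1 (0.58, adjusted p = 0.0085) and the survival gene Bcl2l1 (0.33, adjusted p = 0.0494). The list was higher (camera adjusted p = 0.00883, and adjusted p = 0.333 with an estimated correlation), and adjusted over the list alone 6 rose and 0 fell. Of 10 reactive astrocyte genes, S100a10 rose (0.49, adjusted p = 0.0258) and 3 rose adjusted over the list alone (list median 0.25, adjusted p = 0.00294, and adjusted p = 0.146 with an estimated correlation). Gfap, the intermediate filament of astrocytes, was at 37.1 ± 1.97 FPKM untreated and 44.4 ± 0.62 FPKM at 10 J/cm2 (0.25 ± 0.07, adjusted p = 0.0927). Of 17 astrocyte markers 2 rose, the connexin gene Gjb6 (0.36, adjusted p = 0.0239) and the receptor gene Fgfr3 (0.27, adjusted p = 0.035), and adjusted over the list alone 3 rose and 1 fell (list adjusted p = 0.00883, and adjusted p = 0.33 with an estimated correlation). Of 17 circadian clock genes only Per3 passed over all genes, falling (-0.27, adjusted p = 0.0278), and adjusted over the list alone 3 rose and 9 fell. Dbp, which did not pass over all genes, read 34.48, 32.77 and 36.38 FPKM untreated and 18.68, 23.05 and 20.82 FPKM at 10 J/cm2. Ciart did not pass either, at 11.56, 10.22 and 12.29 FPKM untreated and 5.67, 6.49 and 7.47 FPKM at 10 J/cm2. The circadian list was lower (median -0.20, adjusted p = 0.00883, and adjusted p = 0.333 with an estimated correlation). All 12 inhibitory neuron markers lay above 0 (median 0.16) although 0 passed singly, also adjusted over the list alone (list adjusted p = 0.00883, and adjusted p = 0.206 with an estimated correlation). Of 15 oligodendrocyte markers 0 passed in either count (median -0.10, list adjusted p = 0.00883, and adjusted p = 0.917 with an estimated correlation). Of 10 NF-kB targets 0 passed over all genes and 4 rose adjusted over the list alone (list adjusted p = 0.00883, and adjusted p = 0.42 with an estimated correlation). Leaving out 10 J/cm2 library 3 ended the NF-kB and astrocyte calls (both 0.056), untreated library 3 ended the circadian and oligodendrocyte calls (both 0.0513), and 10 J/cm2 library 2 ended the oligodendrocyte call (0.218). Bcl2l1, Fgfr3 and Per3 lost their calls without any 1 of the 6 libraries (up to 0.163, 0.13 and 0.11), Gjb6 without untreated library 1 or 2 or 10 J/cm2 library 1 or 3 (up to 0.1), and S100a10 without any but untreated library 1 (up to 0.0945).

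Stress genes responded unevenly at 10 J/cm2. Hmox1, the enzyme that degrades heme (ENSMUSG00000005413, chromosome 8 from 75093621 to 75100589), rose from 2.39 ± 0.165 to 4.5 ± 0.276 FPKM (0.70 ± 0.07, adjusted p = 0.00282). It was the only one of 17 Nrf2 targets to pass over all genes, 2 rose and 0 fell adjusted over the list alone, and the list was not called (adjusted p = 0.703). Hspa4l, a member of the Hsp110 chaperones (ENSMUSG00000025757, chromosome 3 from 40744495 to 40796103), rose from 0.486 ± 0.124 to 2.42 ± 0.863 FPKM (1.17 ± 0.19, adjusted p = 0.0172). It was the only one of 20 heat shock chaperones to rise over all genes, and 3 rose and 1 fell adjusted over the list alone. The inducible Hsp70 gene Hspa1a was at 1.89 ± 0.358 and 2.83 ± 0.22 FPKM (0.41 ± 0.26, adjusted p = 0.498). The chaperone list had a camera adjusted p of 0.0259, and adjusted p = 0.917 with an estimated correlation. Alas1, which encodes the enzyme that makes 5-ALA in cells, was at 11.1 ± 0.25 FPKM untreated and 11.2 ± 0.325 FPKM at 10 J/cm2 (0.00 ± 0.05, adjusted p = 0.986), and 0 of 21 heme and porphyrin genes passed in either count. The small membrane protein gene Smim3 (1.08, adjusted p = 0.00862) and the innate immune gene Pglyrp1 (1.05, adjusted p = 0.0132) rose. The microRNA gene Mir666 had 2 to 3 reads in each untreated library and 0 in each library at 10 J/cm2. Leaving out any library but 10 J/cm2 library 3 ended the Hspa4l call (adjusted p up to 0.0784), untreated library 1 or 3 ended that of Pglyrp1 (up to 0.0653), and untreated library 1 or 3 or 10 J/cm2 library 1 ended that of the chaperone list (up to 0.131).

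In total 308 of 14626 genes passed at 10 J/cm2, 211 higher and 97 lower, and 23 of them changed at least 2-fold on the log2(FPKM + 1) scale (13 higher, 10 lower). At an unadjusted p under 0.05 the number was 2334. The 3 libraries of each group did not overlap for all 308 genes, nor for 26.3% of all genes tested, against 10% by chance. The count fell to 84, 125 and 144 without untreated library 1, 2 and 3, and to 123, 162 and 125 without 10 J/cm2 library 1, 2 and 3. In 48 called genes named in the text, single omissions left the fold changes at 0.803 to 1.27 times their full value, and 27 of the 29 calls lost were lost under several omissions. With 6 libraries fitted alone the count was 538, with limma-voom on recovered reads 662 and without a filter on low values 156.

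**Figure D2:**
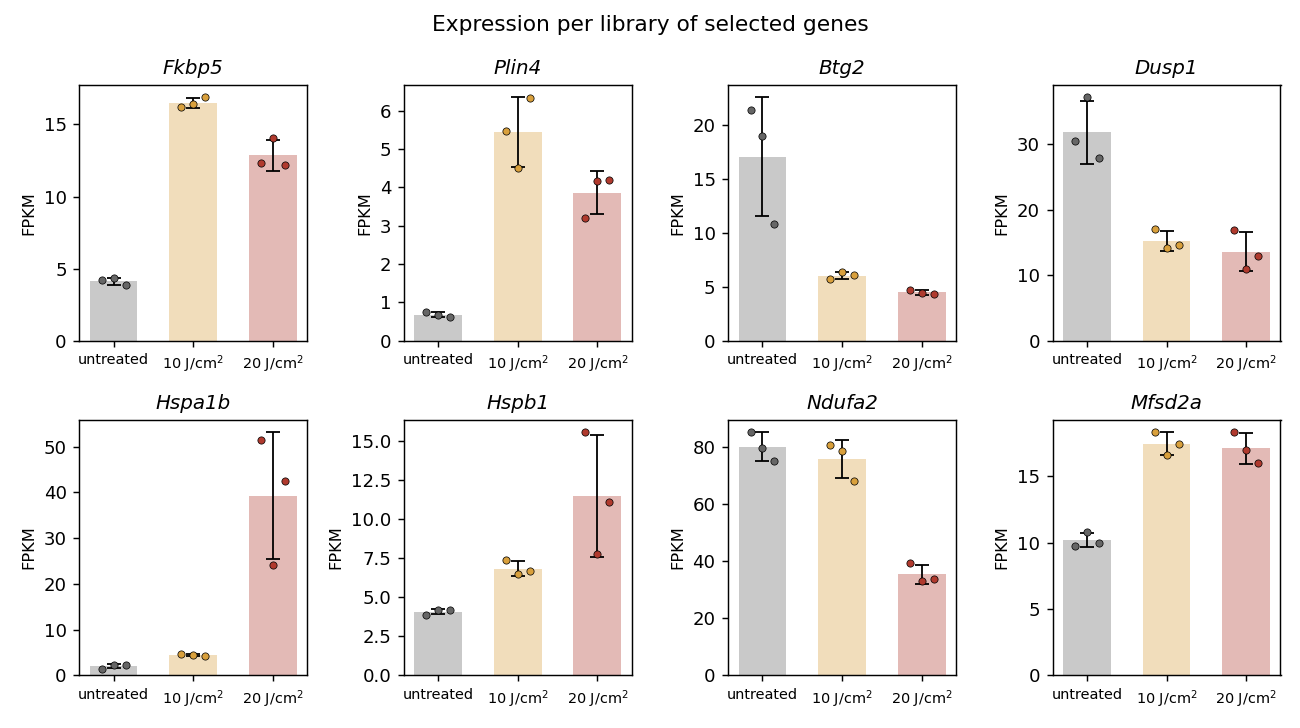
FPKM (vertical axes, starting at 0) of 8 genes in untreated brain and after light at 10 and 20 J/cm2; bars are means, error bars SD (n = 3) and points libraries. Fkbp5, Plin4 and Mfsd2a are above all untreated libraries at both doses, Btg2 and Dusp1 below them at both, and Hspa1b (39.3 FPKM at 20 J/cm2 against 2.01 FPKM untreated) and Ndufa2 (35.3 against 80.0 FPKM) stand apart at 20 J/cm2.

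Comparing 20 J/cm2 with no treatment asks the same of the higher dose. At this dose 25.2% of all genes tested passed, so a list with about that share of members past the threshold does not stand out. Heat shock chaperones rose: of 20 measured, 11 rose, 0 fell and 9 did not pass. The list's median was 0.23 with a camera adjusted p of 2.63e-06, and adjusted p = 0.557 with an estimated correlation. Hspa1b (ENSMUSG00000090877, chromosome 17 from 34956436 to 34959238), an inducible Hsp70 gene, rose from 2.01 ± 0.488 to 39.3 ± 13.9 FPKM (SD, n = 3; 3.69 ± 0.24, adjusted p = 0.000392). Hspa1a (ENSMUSG00000091971, chromosome 17 from 34969190 to 34972156) rose from 1.89 ± 0.358 to 22.8 ± 10.3 FPKM (2.95 ± 0.26, adjusted p = 0.00118). These genes are near-identical neighbours, and how reads were split between them is uncertain. The small heat shock protein gene Hspb1 (1.25 ± 0.19, adjusted p = 0.00369), the constitutive Hsp70 gene Hspa8 (0.59, adjusted p = 0.00363) and the Hsp90 gene Hsp90aa1 (0.51, adjusted p = 0.00193) also rose. There were 14 higher and 0 lower adjusted over the list alone.

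Glucocorticoid-induced genes were higher at 20 J/cm2 as well, with 11 of 13 past the threshold and 0 lower. The list had a median of 0.62 and a camera adjusted p of 2.98e-07, and adjusted p = 0.245 with an estimated correlation. Fkbp5 reached 12.8 ± 1.07 FPKM (1.43 ± 0.06, adjusted p = 4.2e-05), Plin4 3.86 ± 0.566 FPKM (1.53 ± 0.12, adjusted p = 0.000857) and Cdkn1a 20.5 ± 6.12 FPKM (1.55 ± 0.22, adjusted p = 0.00306). Zbtb16 (1.09, adjusted p = 0.00088) and Hif3a (1.16, adjusted p = 0.00116) rose too. There were 11 higher and 1 lower adjusted over the list alone. Immediate early genes moved both ways, with 7 higher and 8 lower of 32, or 8 and 9 adjusted over the list alone, and the list was not called (adjusted p = 0.693). Btg2 fell to 4.47 ± 0.218 FPKM (-1.67 ± 0.20, adjusted p = 0.0022), Dusp1 to 13.6 ± 3.04 FPKM (-1.18 ± 0.15, adjusted p = 0.00258), and Ier2 (-1.20, adjusted p = 0.00335) and Junb (-1.14, adjusted p = 0.00379) fell with them. Fos was at 41.8, 13.6 and 31.7 FPKM in the libraries at 20 J/cm2 (-0.31 ± 0.33, adjusted p = 0.525), and its difference was 0.14 without library 2. Circadian clock genes moved both ways too, with 3 higher and 4 lower of 17, or 3 and 7 adjusted over the list alone. That list was not called (camera adjusted p = 0.622).

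Nuclear-encoded genes of oxidative phosphorylation fell at 20 J/cm2, with 18 of 38 lower, 0 higher and 20 not past the threshold. The list median was -0.19 (camera adjusted p = 4.05e-05, and adjusted p = 0.557 with an estimated correlation). Ndufa2, a complex I subunit (ENSMUSG00000014294, chromosome 18 from 36742332 to 36744557), fell from 80.0 ± 5.04 to 35.3 ± 3.34 FPKM (-1.16 ± 0.08, adjusted p = 0.000764). The complex IV subunit gene Cox8a (-0.50, adjusted p = 0.00241) and the complex I subunit genes Ndufb3 (-0.53, adjusted p = 0.00335) and Ndufv1 (-0.31, adjusted p = 0.00342) fell, as did Atp5k of ATP synthase (-1.61 ± 0.36, adjusted p = 0.0131), which read 36.8, 20.2 and 9.63 FPKM in the 3 libraries. The count adjusted over the list alone was 3 higher and 21 lower. Of 42 ribosomal protein genes 19 fell and 4 rose, including the lower Rpl38 (-0.70, adjusted p = 0.00235), Rps29 (-0.81, adjusted p = 0.00321) and Rpl11 (-0.55, adjusted p = 0.00321) and the higher Rplp0 (0.39, adjusted p = 0.00289). The other higher genes, named after their values were seen, were Rpsa (0.28, adjusted p = 0.0073), Rpl7 (0.18, adjusted p = 0.0166) and Rps24 (0.17, adjusted p = 0.0385). Adjusted over the list alone 6 rose and 21 fell (list median -0.18, camera adjusted p = 0.000418, and adjusted p = 0.557 with an estimated correlation). Of 13 protein genes of the mitochondrial genome 6 rose and 0 fell, with the same counts adjusted over the list alone. They included the oxidase subunit gene mt-Co1 (0.37, adjusted p = 0.00786), mt-Nd5 (0.46, adjusted p = 0.0125), mt-Nd6 (0.52, adjusted p = 0.0154) and mt-Cytb (0.31, adjusted p = 0.0262). That list's median was 0.25 (camera adjusted p = 0.0452, and adjusted p = 0.67 with an estimated correlation), and 0 under quantile normalization, where mt-Co1 and mt-Cytb differ by 0. Genes that keep their rank get the same value in every library under that method, so these values of 0 do not count against the rise. These 3 lists moved in the libraries whose fold changes followed GC content (rho = -0.332, -0.492 and -0.521 for libraries 1, 2 and 3) and whose mitochondrial share of reads was 3.88%, 4.62% and 4.74%. After each library's trend with GC content and length was removed, the mitochondrial list no longer passed (median 0.09, adjusted p = 0.062) although 3 of its 6 called genes did, among them mt-Co1 (0.26, adjusted p = 0.0159), while the other lists did (medians -0.15 and -0.13, adjusted p = 6.02e-05 and 0.0247). The mitochondrial list was also lost without untreated library 3 (0.217), 20 J/cm2 library 2 (0.0684) or library 3 (0.0598), mt-Nd6 without untreated library 1 or 2 (up to 0.0583), and mt-Cytb without untreated library 2 or 3, 20 J/cm2 library 2 or 3 (up to 0.0923) or the trend (0.20 ± 0.06, 0.0778). Rpl7 lost its call without untreated library 1 or 2 or 20 J/cm2 library 3 (up to 0.0668) or the trend (0.10 ± 0.03, 0.0866), and Rps24 without any library but 20 J/cm2 library 1 (up to 0.116) or the trend (0.04 ± 0.04, 0.624).

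Glial and vascular genes also differed at 20 J/cm2. Of 15 oligodendrocyte markers 7 fell and 0 rose, the same adjusted over the list alone, among them the myelin genes Cnp (-0.47, adjusted p = 0.00322), Mag (-0.52, adjusted p = 0.00595), the connexin gene Gjb1 (-0.56, adjusted p = 0.00586) and the claudin gene Cldn11 (-0.28, adjusted p = 0.0129). The list's median was -0.20 (camera adjusted p = 0.0196, and adjusted p = 0.67 with an estimated correlation). Of 10 reactive astrocyte genes 5 rose, namely Hspb1, Gfap (46.1 ± 4.11 FPKM; 0.30, adjusted p = 0.0118), the protease inhibitor gene Serpina3n (0.39, adjusted p = 0.027), the lipopolysaccharide co-receptor gene Cd14 (0.74, adjusted p = 0.0407) and Cp (0.35, adjusted p = 0.0415), the last named after its values were seen. Adjusted over the list alone 6 rose and 0 fell (list median 0.26, camera adjusted p = 0.0146, and adjusted p = 0.342 with an estimated correlation). Cldn5 fell to 11.1 ± 3.08 FPKM (-0.93 ± 0.18, adjusted p = 0.00857), with Cgn (-0.38, adjusted p = 0.0233) and Cgnl1 (-0.27, adjusted p = 0.0282) the other 2 of 17 junction genes lower, 0 being higher and the counts being the same adjusted over the list alone (list adjusted p = 0.715). Mfsd2a (0.69, adjusted p = 0.00118), Slc2a1 (0.58, adjusted p = 0.0022) and Abcc4 (0.42, adjusted p = 0.00585) were again higher and Slco1a4 (-0.52, adjusted p = 0.00369) lower. With Tfrc (0.32), Slc22a8 (-0.80) and Slc16a1 (-0.37), named after their values were seen, 4 of 17 barrier transporters rose and 3 fell, the same adjusted over the list alone (list adjusted p = 0.693). Of 17 endothelial markers 1 rose, Ly6c1 (0.45, adjusted p = 0.0044), and 7 fell, including Kdr (-0.55, adjusted p = 0.00481), or 1 and 8 adjusted over the list alone (list adjusted p = 0.062). Col4a1 (0.68, adjusted p = 0.00132), Lamc1 (0.40, adjusted p = 0.00412) and Timp3 (0.50, adjusted p = 0.0044) rose and the protease gene Adamts4 fell (-0.50, adjusted p = 0.00537). Together with Adamts1 (0.45), Col4a2 (0.27), Agrn (-0.22), Hspg2 (-0.28) and Lamb2 (-0.23), named after their values were seen, 5 of 19 matrix genes rose and 4 fell, the same adjusted over the list alone (list adjusted p = 0.693). Removing the trend ended some calls (log2 difference ± SE after removal): Gjb1 (-0.39 ± 0.11, adjusted p = 0.0522), Cgn (-0.31 ± 0.09, 0.0607), Cp (0.17 ± 0.10, 0.282) and Tfrc (0.14 ± 0.08, 0.274). Matrix genes were Agrn (-0.13 ± 0.05, 0.0909), Hspg2 (-0.15 ± 0.09, 0.297) and Lamb2 (-0.09 ± 0.07, 0.428). Leaving out 1 library ended the oligodendrocyte call (untreated 3, 0.0685; 20 J/cm2 2, 0.0593) and those of Serpina3n (any untreated, up to 0.0826), Cd14 (any but 20 J/cm2 2, up to 0.129), and Cp (any but 20 J/cm2 1, up to 0.124). Junction and transporter calls lost this way were Cgn (any untreated or 20 J/cm2 3, up to 0.0791), Cgnl1 (any but 20 J/cm2 3, up to 0.102), Tfrc (untreated 1 or 2 or 20 J/cm2 3, up to 0.0726), and Slc16a1 (untreated 1 or 2, up to 0.0721). Matrix calls lost this way were Col4a2 (any but 20 J/cm2 2, up to 0.113), Agrn (any but 20 J/cm2 1, up to 0.0913), Hspg2 (any, up to 0.12) and Lamb2 (any but 20 J/cm2 2, up to 0.106).

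Hmox1 reached 4.97 ± 0.351 FPKM at 20 J/cm2 (0.82 ± 0.07, adjusted p = 0.00116), and of 17 Nrf2 targets 3 rose and 2 fell, the same adjusted over the list alone (list adjusted p = 0.559). The others, named after their values were seen, were the glutathione synthesis gene Gclc (0.22, adjusted p = 0.00677), the peroxiredoxin gene Prdx1 (0.19, adjusted p = 0.0166), the thioredoxin gene Txn1 (-0.51, adjusted p = 0.0105) and the autophagy receptor gene Sqstm1 (-0.15, adjusted p = 0.0326). Alas1 was at 11.3 FPKM (0.03 ± 0.05, adjusted p = 0.75). Of 21 heme and porphyrin genes 5 fell and 1 rose, the transferrin receptor gene Tfrc, the same adjusted over the list alone (list adjusted p = 0.618, with 25.2% of all genes past the threshold). The fallen genes, named after their values were seen, were Ppox (-0.28), Cpox (-0.28) and Urod (-0.18), enzymes of heme synthesis, the mitochondrial membrane protein gene Tspo (-0.40) and the heme transporter gene Slc48a1 (-0.16). With the GC and length trend removed Tspo (-0.18 ± 0.11, adjusted p = 0.335), Urod (-0.09 ± 0.05, 0.251), Slc48a1 (-0.02 ± 0.03, 0.679), Prdx1 (0.08 ± 0.03, 0.156) and Sqstm1 (-0.07 ± 0.04, 0.271) no longer passed. Leaving out 1 library ended the calls of Tspo (any untreated or 20 J/cm2 3, up to 0.0766), Cpox (untreated 1 or 2 or 20 J/cm2 2 or 3, up to 0.0948), Urod (untreated 1 or 2 or 20 J/cm2 1 or 3, up to 0.105) Slc48a1 (any but 20 J/cm2 1, up to 0.109), Prdx1 (untreated 1 or 20 J/cm2 3, up to 0.0672) and Sqstm1 (untreated 1 or 2 or 20 J/cm2 2 or 3, up to 0.116). Rps6kb2, a kinase of ribosomal protein S6, rose (1.54 ± 0.33, adjusted p = 0.0122), and Gstp1, a glutathione transferase with a near-identical paralog (-1.34 ± 0.30, adjusted p = 0.0143), and Gkn3 (8 to 25 reads per library; -1.44 ± 0.20, adjusted p = 0.00327) fell. The other genes with the largest changes were short RNAs with few reads. Rn7sk had 10 to 22 reads per untreated library and 49 to 56 at 20 J/cm2, mt-Ti 1 to 5 and 8 to 9, and Mir5621 0 to 1 and 2 to 3. Mir7052 had 26 to 35 and 6 to 10 reads, mt-Tl2 95 to 139 and 35 to 42, Mir6908 3 to 5 and 0 to 2, and Mir26b 2 to 3 and 0. Mir6908 was lost without any library but 20 J/cm2 library 1 (adjusted p up to 0.111) and without the trend (-1.14 ± 0.42, 0.108).

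In total 3691 genes passed at 20 J/cm2, 1852 higher and 1839 lower, and 65 of them changed at least 2-fold (29 higher, 36 lower). At an unadjusted p under 0.05 the number was 5630. Of the 3691 genes 99.2% had no overlap between groups, and 41.4% of all genes had none, against 10% by chance. With the GC and length trend removed 1852 passed, of which 1506 were among the 3691 (40.8%). With the 6 libraries fitted alone 2616 passed. The main fit shared 1 spread per gene over all groups, while pairs at 20 J/cm2 differed most, so p-values at this dose may be too small. In 100 called genes named in the text, single omissions left the fold changes at 0.644 to 1.36 times their full value, and all 25 calls lost were lost under several omissions. The count was 1874 and 2015 without untreated library 1 and 2, 2131 without 20 J/cm2 library 3, and 844 without both 20 J/cm2 libraries of highest mitochondrial share, which leaves 1 library at that dose.

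**Figure D3:**
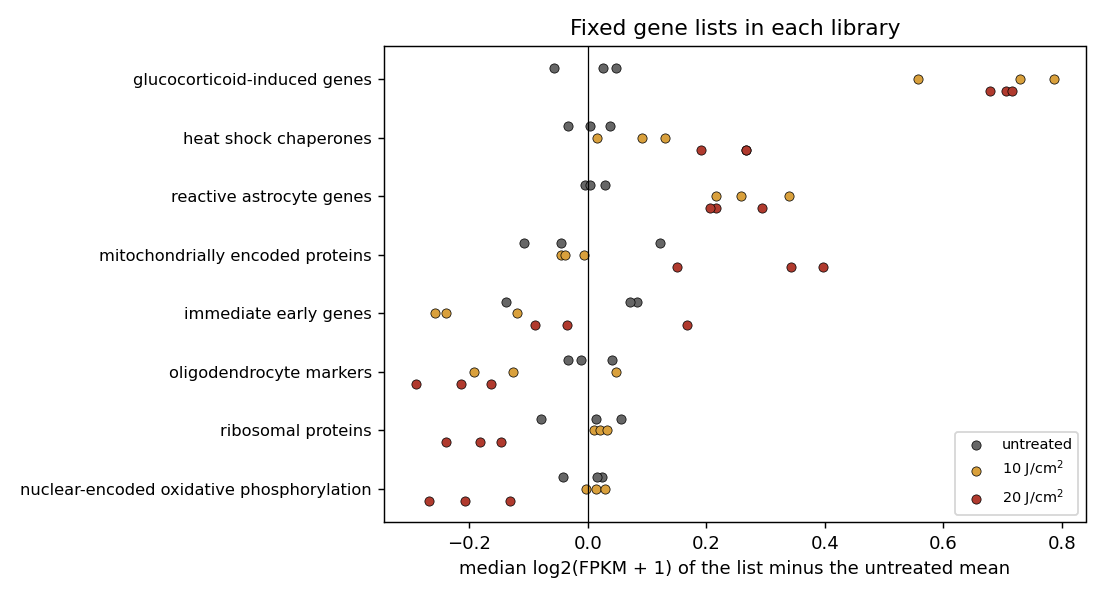
Median log2(FPKM + 1) of 8 fixed gene lists in each library, relative to the mean of the untreated libraries (horizontal axis); each point is a library, coloured by group, and each line a list. Glucocorticoid-induced genes lie at 0.56 to 0.79 in all treated libraries, and nuclear-encoded oxidative phosphorylation genes lie at -0.13 to -0.27 at 20 J/cm2. The mitochondrially encoded list, apart at 20 J/cm2, has a fold-change median of 0 under quantile normalization. That method gives genes that keep their rank the same value in every library, so this 0 does not count against the rise.

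Genes called at both doses went the same way: 258 passed in both comparisons with untreated, 172 higher in both and 86 lower in both, and 0 in opposite directions. They made up 83.8% of the 308 genes called at 10 J/cm2, and 306 of the 308 had the same sign at 20 J/cm2. Both comparisons share the 3 untreated libraries. All 9 libraries were also simulated with no difference between groups, which gave 0.02 shared calls on average over 50 simulations. With no true change hardly any gene is called, so this does not show how many of the 258 come from shared controls. Independent lists of these sizes would share 38.9 (26.7 higher, 12.2 lower). Across genes, which are not independent replicates, the fold changes correlated at r = 0.562 against 0.505 simulated, with a covariance of 0.0295 against 0.00933 simulated, a difference of 0.0201 net of the shared controls. Part of the excess of shared calls over independent lists may come from the shared controls, which are too few to split. The overlap was 75, 106 and 128 without untreated library 1, 2 and 3, and 498 with limma-voom on recovered reads.

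Comparing 20 with 10 J/cm2 tests directly how the doses differ. Heat shock chaperones were higher at 20 J/cm2, with 10 of 20 higher, 1 lower and 9 not past the threshold. The list median was 0.25 (camera adjusted p = 1.41e-05, and adjusted p = 0.768 with an estimated correlation). Hspa1b rose from 4.47 ± 0.274 to 39.3 ± 13.9 FPKM (2.82 ± 0.24, adjusted p = 0.00403) and Hspa1a from 2.83 ± 0.22 to 22.8 ± 10.3 FPKM (2.54 ± 0.26, adjusted p = 0.00704). Hsp90aa1 (0.46, adjusted p = 0.00742) and the co-chaperone gene Dnajb1 (0.40, adjusted p = 0.0192) were higher, and Hspa4l fell from 2.42 ± 0.863 to 0.58 ± 0.221 FPKM (-1.09 ± 0.19, adjusted p = 0.0197). Adjusted over the list alone 12 were higher and 1 lower. Of 13 glucocorticoid-induced genes only Fkbp5 differed (-0.34, adjusted p = 0.0224), also adjusted over the list alone, and the list was not called (adjusted p = 0.314). Plin4 (-0.41, adjusted p = 0.0629), Ddit4 (-0.47, adjusted p = 0.128) and Tsc22d3 (-0.16, adjusted p = 0.247) did not pass. Without 10 J/cm2 library 1 or 2 or 20 J/cm2 library 3 the calls of Fkbp5 (up to 0.0743), Hspa4l (up to 0.0729) and Dnajb1 (up to 0.0719) ended, and that of Fkbp5 also without 10 J/cm2 library 3.

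Nuclear-encoded oxidative phosphorylation genes were lower at 20 than at 10 J/cm2, with 17 of 38 lower and 0 higher, or 20 and 0 adjusted over the list alone. The list had a median of -0.20 (camera adjusted p = 2.77e-08, and adjusted p = 0.768 with an estimated correlation). Ndufa2 (-1.08 ± 0.08, adjusted p = 0.0031), Cox7b (-0.35, adjusted p = 0.00741), Cox5b (-0.53, adjusted p = 0.012), Ndufb3 (-0.57, adjusted p = 0.0123) and Atp5k (-1.71 ± 0.36, adjusted p = 0.0258) fell. Of 42 ribosomal protein genes 16 were lower and 1 higher, or 21 and 4 adjusted over the list alone (list median -0.21, camera adjusted p = 7.55e-06, and adjusted p = 0.768 with an estimated correlation). Rps29 (-1.04, adjusted p = 0.00704), Rpl38 (-0.79, adjusted p = 0.00704), Rpl11 (-0.49, adjusted p = 0.0174) and Rps18 (-0.51, adjusted p = 0.0174) fell, and Rplp0 rose (0.24, adjusted p = 0.0307), the last named after its values were seen. Rps18 read only 3.295, 3.169 and 2.997 FPKM at 10 J/cm2 and 1.645, 2.139 and 1.955 FPKM at 20 J/cm2. The ribosomal protein gene Rps15 read 330.2, 346.9 and 342.8 FPKM at 10 J/cm2. How reads were assigned among similar sequences was not tested. Of 13 mitochondrially encoded protein genes 3 were higher and 0 lower, or 7 and 0 adjusted over the list alone: mt-Co1 (0.40, adjusted p = 0.0199), mt-Nd5 (0.47, adjusted p = 0.0272) and mt-Cytb (0.37, adjusted p = 0.032). That list's median was 0.35 (camera adjusted p = 0.00326, and adjusted p = 0.768 with an estimated correlation). It was 0.13 under quantile normalization, which takes away differences of genes that keep their rank. Among short RNAs the 20 J/cm2 libraries held more reads of Rn7sk (49 to 56 against 13 to 23 per library), mt-Ts2 (13 to 35 against 2 to 10) and Snora34 (14 to 16 against 3 to 8), and fewer of mt-Tl2 (35 to 42 against 63 to 123) and Mir3093 (2 to 3 against 7 to 9). The mitochondrial share of reads was 4.41 ± 0.466% at 20 against 3.49 ± 0.062% at 10 J/cm2 (exact two-sided permutation p = 0.1), and fold changes followed GC content (rho = -0.552).

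Many calls in this comparison were lost with 1 library fewer, mostly under several different omissions (16 of the 17 named genes that lost theirs), while fold changes stayed at 0.717 to 1.29 times their full value. Ndufb3 ranged from -0.50 to -0.63, Rps18 from -0.45 to -0.57, Rpl11 from -0.43 to -0.56 and mt-Co1 from 0.35 to 0.48. With 10 J/cm2 library 1 or 2 left out the calls of Ndufb3 (adjusted p up to 0.0565), Rps18, Rpl11 (both up to 0.0719), mt-Co1 (up to 0.0774), mt-Nd5 (up to 0.0967), mt-Cytb (up to 0.111), Rplp0 (up to 0.103), Atp5k (up to 0.0861), mt-Tl2 (up to 0.0743), mt-Ts2 (up to 0.119), Snora34 (up to 0.0805) and Mir3093 (up to 0.116) ended, and with 10 J/cm2 library 1 that of Rn7sk (0.0636). Other libraries ended some of these too, 20 J/cm2 library 3 for all of them but Ndufb3, Atp5k and Rn7sk. It was 20 J/cm2 library 2 for mt-Nd5, mt-Cytb, Rplp0, Atp5k, Snora34 and Mir3093, and 10 J/cm2 library 3 for mt-Nd5, mt-Cytb, Rplp0, Atp5k, mt-Ts2, Snora34 and Mir3093, and 20 J/cm2 library 1 for Mir3093. Removing the trend ended further calls while much of the folds stayed, 71.3% in mt-Nd5 and 75.3% in mt-Cytb (log2 difference ± SE after removal). These were Atp5k (-1.54 ± 0.35, adjusted p = 0.0603), mt-Nd5 (0.33 ± 0.08, 0.0646), mt-Cytb (0.28 ± 0.06, 0.0694), mt-Ts2 (1.72 ± 0.46, 0.0955), Snora34 (1.12 ± 0.27, 0.0758) and Mir3093 (-0.97 ± 0.30, 0.142). Fewer genes passed after removal, which by itself raises adjusted p. In total 1329 genes passed, 577 higher and 752 lower, 32 of them at least 2-fold (8 higher, 24 lower) and 4307 at an unadjusted p under 0.05. Of the 1329 genes 99.9% had no overlap between groups, and 31.8% of all genes had none, against 10% by chance. The count was 43, 49 and 549 without 10 J/cm2 library 1, 2 and 3, and 2497, 811 and 131 without 20 J/cm2 library 1, 2 and 3. With the trend removed it was 313, of which 270 were among the 1329 (20.3%), and with the 6 libraries fitted alone it was 67.

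Markers of brain regions were not called as lists, with 4 to 11 members each. For hippocampus, striatum, thalamus and midbrain, hypothalamus and cerebellum the lowest camera adjusted p was 0.704 at 10 J/cm2, 0.228 at 20 J/cm2 and 0.295 between the doses. At 20 J/cm2 all 4 cerebellum markers lay below 0 (median -0.28, adjusted p = 0.228, and 0.0452 with fry), with the transcription factor genes Zic1 (-0.56, adjusted p = 0.0447) and Zic2 (-0.42, adjusted p = 0.0222) lower, also adjusted over the list alone. All 5 thalamus and midbrain markers lay below 0 too (median -0.29, adjusted p = 0.302), with 0 past the threshold. These medians are further from 0 than that of the oligodendrocyte list (-0.20), which was called at the preset correlation only (adjusted p = 0.67 with an estimated correlation). Against 10 J/cm2 the medians were -0.42 and -0.35, and Zic2 was lower (-0.44, adjusted p = 0.0402). Of 9 meningeal fibroblast markers only Islr was lower at 20 J/cm2 (-0.60, adjusted p = 0.028), also adjusted over the list alone (list median -0.32, adjusted p = 0.228). Zic1, Zic2 and Islr were named after their values were seen. Removing the trend ended the calls of Zic2 (-0.23 ± 0.11, adjusted p = 0.19 against untreated; -0.28 ± 0.11, 0.21 against 10 J/cm2) and Islr (-0.46 ± 0.17, 0.106). Leaving out 1 library ended those of Zic1 (untreated 1 or 2 or 20 J/cm2 1 or 2, up to 0.142), Zic2 (untreated 1 or 20 J/cm2 3, up to 0.0791; against 10 J/cm2 any at 10 J/cm2 or 20 J/cm2 3, up to 0.105) and Islr (untreated 1 or 2 or 20 J/cm2 1 or 3, up to 0.0953). Relative to the untreated mean, 20 J/cm2 library 2 stood apart from libraries 1 and 3 in the medians of choroid plexus (0.61 against -0.01 and 0.04), hypothalamus (0.50 against -0.24 and -0.22) and meningeal markers (0.16 against -0.48 and -0.56). The labels name no brain region. The lists of blood leukocytes had too few measured members to test, with 2 of 15 neutrophil and monocyte genes and 2 of 13 T and B cell genes at 1 FPKM or more in 3 libraries. Their highest values in any library were 5.55 FPKM for Lyz2 and 5.59 FPKM for Ighm. Of the 39 lists tested, 28, 32 and 35 were not called at 10 J/cm2, at 20 J/cm2 and between the doses, and the lowest adjusted p among them were 0.121, 0.062 and 0.145.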

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

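The settings limma-voom, trend removal, genes of 300 bases or more, median scaling and omission of both 20 J/cm2 libraries 2 and 3 were tests chosen only after the results were seen. The plan tied another count test and other size factors to a deposited count table, and they were not run; recovered reads were tested with limma-voom only. The deposited depth limits what can be said on short RNAs with few reads, and the 2 libraries left in a group after a single omission borrow their spread from the other groups. Without both 20 J/cm2 libraries 2 and 3 the arm has 1 library, which is assumed to vary like the other groups. Against that assumption, pairs at 20 J/cm2 differed more (chi-square 7.02 to 9.71 per gene) than pairs within the other groups (2.98 to 3.86). Counts of changed genes were 308 at 10 J/cm2, 3691 at 20 J/cm2 and 1329 between the doses. They stayed within 1.5 times under quantile normalization (304, 3655, 1374), a filter of 5 FPKM (291, 3279, 1835), a pseudocount of 0.1 (305, 3665, 1332), genes of 300 bases or more (364, 3810, 1592), median scaling (303, 3681, 1362) and the replicate block (220, 3518, 1357). With a log2 fold change of at least 1 they were 23, 65 and 32, by construction. Without a filter they were 156, 2430 and 329, with 32727 genes to adjust over. With the 6 libraries alone they were 538 at 10 J/cm2, 2616 at 20 J/cm2 and 67 between the doses. With limma-voom they were 662 at 10 J/cm2 and 2069 between the doses. With the trend removed they were 1852 at 20 J/cm2 and 313 between the doses, and without both 20 J/cm2 libraries 2 and 3 they were 844 and 8. The fits of 6 libraries moved opposite ways, up at 10 J/cm2 and down at 20 J/cm2 and between the doses. Fewer libraries alone therefore do not account for both directions. The fit at 10 J/cm2 left out the 20 J/cm2 libraries, whose pairs differed most. The fit between the doses left out the untreated libraries. In the main fit 1 spread per gene was shared over all groups, which may be too small for 20 J/cm2. P-values that involve 20 J/cm2 may then be too small. What moved the counts in these settings was not tested. Leaving out 1 library gave 84 to 162 at 10 J/cm2, 1874 to 4052 at 20 J/cm2 and 43 to 2497 between the doses. The overlap was counted only with an untreated library left out, and was then 75 to 128 against 258. The overlap was 498 with limma-voom, 310 with the trend removed and 186 with the block.

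Called lists numbered 11, 7 and 4. With an estimated correlation 1, 0 and 0 were called. That setting widens the error of lists whose members vary together, and it also tests on far fewer degrees of freedom. Which of these ended the calls was not tested. With fry 8, 19 and 3 were called, without a filter 12 at 20 J/cm2 and 7 between the doses, and without both 20 J/cm2 libraries 2 and 3 there were 11 at 20 J/cm2 (the cause was not tested). Leaving out 1 library gave 8 to 12, 5 to 8 and 4 to 6. Limma-voom kept all 22 list calls. The block ended the endothelial list at 10 J/cm2 (adjusted p = 0.0515), the mitochondrially encoded list at 20 J/cm2 (0.0711) and 17 of 173 calls of named genes, and changed no other list call. The plan had fixed beforehand that numbers were not treated as pairs, since the labels give no batch. Libraries of the same number did not resemble each other across groups (r -0.068 to 0.056, against -0.059 to 0.050 for different numbers). Of the libraries, 0 matched their own number best in both other groups. Of 173 named gene calls 168 held with limma-voom, 147 with the trend removed, 169 with a pseudocount of 0.1, 160 with quantile normalization, 138 with 6 libraries and 120 without a filter. With 1 library at 20 J/cm2, 60 held and 65 did not. Values that reversed were those of Alas1 at 10 J/cm2 (-0.003 with quantile normalization, -0.008 without untreated library 3, -0.011 and -0.002 without 10 J/cm2 library 1 and 2) and at 20 J/cm2 (-0.019 without library 1), all near 0, with ranges over single omissions of -0.011 to 0.026 and -0.019 to 0.056. Olig2 at 10 J/cm2 ranged from -0.161 to 0.002 and Olig1 at 20 J/cm2 from -0.077 to 0.09 over single omissions (Olig1 was also -0.012 and -0.005 without untreated library 1 and 3), and neither passed. Fos at 20 J/cm2 ranged from -0.632 without library 1 to 0.144 without library 2 and was 0.337 without libraries 2 and 3, and the cause was not tested. Quantile normalization set mt-Co1 to 0 against untreated and against 10 J/cm2, by construction, since it ranked first in every library.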

Other observations

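The tests of endothelial and astrocyte shares below were chosen only after the results were seen. Several genes outside the naming rule were picked singly after their values were seen, and were not tested as a group. Nr3c1, the glucocorticoid receptor gene, fell at 10 J/cm2 (-0.55, adjusted p = 0.00183) and at 20 J/cm2 (-0.34, adjusted p = 0.00333), while the glucocorticoid-induced genes rose. Xdh, which encodes xanthine dehydrogenase (1.04 and 0.76, adjusted p = 0.000803 and 0.00145), and the uncoupling protein gene Ucp2 (0.74 and 0.64, adjusted p = 0.00166 and 0.00147) rose at both doses, as did the dexamethasone-induced Ras gene Rasd1 (0.91 and 0.82, adjusted p = 0.0334 and 0.0112) and the thyroid hormone deiodinase gene Dio2 (0.81 and 1.01, adjusted p = 0.0146 and 0.00246). The adrenergic receptor gene Adrb1 (-0.67 and -0.56, adjusted p = 0.00183 and 0.00193) and the chemokine gene Cxcl12 (-0.61 and -0.80, adjusted p = 0.0162 and 0.00241) fell at both. At 10 J/cm2 Rasd1 lost its call without untreated library 1 or 3 or 10 J/cm2 library 1 or 3 (adjusted p up to 0.127), Dio2 without untreated library 1 or 2 or 10 J/cm2 library 1 or 3 (up to 0.0705) and Cxcl12 without any but untreated library 2 (up to 0.0766).

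Some genes of the oligodendrocyte lineage, picked singly, fell at both doses: Sox10 (-0.56 and -0.59, adjusted p = 0.00839 and 0.00258), the neuregulin receptor gene Erbb3 (-0.51 and -0.71, adjusted p = 0.0127 and 0.00193) and Nkx6-2 (-0.37 and -0.74, adjusted p = 0.0306 and 0.00129), along with the progenitor factor Sox2 (-0.40 and -0.54, adjusted p = 0.0252 and 0.00278). The lineage regulators Olig1 (0.17 and 0.01, adjusted p = 0.371 and 0.92) and Olig2 (-0.06 and -0.22, adjusted p = 0.834 and 0.142) did not pass. Of 11 oligodendrocyte precursor markers only Sox10 was lower at each dose, also adjusted over the list alone, and that list was not called (adjusted p = 0.636 and 0.355). At 10 J/cm2 Erbb3 lost its call without untreated library 2 or 3 or 10 J/cm2 library 2 or 3 (up to 0.057), Nkx6-2 without any 1 of the 6 libraries (up to 0.114) or the GC and length trend (-0.35 ± 0.08, 0.0591), and Sox2 without any but 10 J/cm2 library 2 (up to 0.103). At 20 J/cm2 the immediate early genes Maff (1.17, adjusted p = 0.0108), Atf3 (1.004, adjusted p = 0.00537) and Gadd45b (0.74, adjusted p = 0.00754) rose while Btg2 and Junb fell. Among the 1839 lower genes at 20 J/cm2 were, picked singly and not tested as a group, Tomm7 (-0.82, adjusted p = 0.00375), Timm13 (-0.82, adjusted p = 0.00381), Romo1 (-0.80, adjusted p = 0.00703) and Mrpl14 (-0.83, adjusted p = 0.00193).

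Glucocorticoid-induced genes were higher at both doses in all treated libraries. A trend of the libraries with GC content and length would have taken the difference away, but 92.4% of the median was kept at the dose that kept less (20 J/cm2: 0.62 to 0.57, adjusted p = 4.74e-10). At 20 J/cm2 the camera call rests on the preset correlation (adjusted p = 0.245 with an estimated correlation), at 10 J/cm2 it does not (0.0308). Fry, which uses no preset correlation, also called the list at 20 J/cm2 (fry adjusted p = 0.000188). It asks whether members changed at all, not whether they changed more than other genes. Endothelial and astrocyte markers had upper quartiles of at most 0.116 and 0.243, below the glucocorticoid medians of 0.67 and 0.62. Astrocyte markers were themselves higher, with medians of 0.089 at 10 J/cm2 (list called) and 0.125 at 20 J/cm2 (camera adjusted p = 0.0933). A larger share of these cells that moved all their transcripts alike would thus not reach the glucocorticoid rise. A smaller rise in the share of astrocytes is not excluded. The result is consistent with a stress hormone response, which handling, anaesthesia or the treatment itself may have caused, and these stay confounded with group since the handling of untreated mice is not stated.

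Heat shock chaperones rose at 20 J/cm2. The list kept 91.8% of its median with the trend removed (0.23 to 0.21, adjusted p = 2.78e-07), and with any library at 20 J/cm2 left out its adjusted p was at most 6.29e-05. These p rest on the preset correlation, and the list did not pass with an estimated correlation (adjusted p = 0.557). Fry called the list (fry adjusted p = 0.00599), but asks only whether members changed at all. Neither a GC trend nor a single library accounts for the rise of the list. Protein damage by photodynamic oxidation and warming of tissue by the laser may each induce these genes, and no library separates them.

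The nuclear-encoded oxidative phosphorylation list was lower at 20 J/cm2 (18 of 38 genes lower, 0 higher). So was the ribosomal protein list (19 of 42 lower, 4 higher), while the mitochondrially encoded list was higher (6 of 13 higher, 0 lower). The camera calls of these lists rest on the preset correlation (camera adjusted p = 0.557, 0.557 and 0.67 with an estimated correlation). Fry called each of them (fry adjusted p = 0.00567, 0.0167 and 0.0463), but asks only whether members changed at all. With the GC and length trend removed the first list kept 81.3% of its median and the second 74%. The mitochondrial list kept 36.9% (0.25 to 0.09, camera adjusted p from 0.0452 to 0.062). Its median is the value of mt-Nd4, and the 6 called members kept 59.5% to 71.2% each. The trend may thus account for the list's call. Part of the rise of its genes stayed: 3 of the 6 called members still passed, and mt-Co1 kept 0.26 of 0.37 against untreated and 0.31 of 0.40 against 10 J/cm2. The removal may be incomplete, since 10.1% of calls after it were false in data simulated with a GC trend, against 4.6% without a trend. Whether the trend made the whole rise can therefore not be told. Among 10000 lists matched in length, GC content and expression, the median of the first list (-0.19, against -0.01 for matched lists) lay at percentile 0 and that of the second (-0.18, against -0.03) at percentile 0.02. An effect tied to such gene length, GC content and expression therefore does not by itself account for these lists. Length here is the gene length of the deposited table (list medians 1918 and 1800 bases), which may differ from that of the transcripts present. An effect on short transcripts as such was thus not tested. As given above, the camera calls of these lists rest on the preset correlation. The labels give no preparation batches, so a batch difference of another kind was not tested.

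In the 10 ways to split 6 libraries the real groups called 308, 3691 and 1329 genes and the highest other split 2, 1 and 2; with 10 splits the share cannot be under 0.05.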
